A study of Rattus norvegicus with 18 samples.

How the data were processed

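The data are gene expression profiles of cells sorted by flow cytometry from dissociated brains of male rat pups at postnatal day 7. Per the labels, 5 biological replicates of A2B5+ cells and 4 of O4+ cells were prepared, each from a litter of 10 pups, and total RNA was labelled with biotin. Each replicate has a column on 2 array types, called array A and array B here, which gives 18 arrays in 9 columns per type. Samples were grouped by the antigen in their titles.

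The values are linear ratios, as the authors deposited them. GCRMA, a background correction and summary of Affymetrix probe sets, is named without a version in the submitters' processing notes; how the ratios were made from its output is not given in the sources used here. The files show that the median of a probe set's 9 ratios was exactly 1 for 12995 of 15923 probe sets on array A and 11050 of 15333 on array B, and below 1 for all others. Such values would arise where each probe set is divided by its own median or, when that median is low, by a fixed minimum, but no header records it. Differences between arrays can therefore be read for a probe set, while levels of different probe sets cannot be compared. As a check chosen after seeing the data, the median pattern over the 9 arrays of probe sets with a median ratio under 1 was subtracted. The residual SD of these probe sets had a median of 0.065 on array A and 0.061 on array B, against 0.39 and 0.35 in those with a median of 1. All A2B5+ ratios lay below 1 for 76 probe sets called higher on array A and 20 on array B, and for these the size of the difference is uncertain. The O4+ residual SD was under 0.1 for 77 probe sets called lower on array A and 83 on array B. The precision is limited by the number of arrays.

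The test planned before the data were examined assumed log2 levels, with probe sets kept at a log2 value above 4 on at least 4 of 9 arrays and the brightest probe set standing for a gene. No such level is left in ratios. The log2 of each ratio was used without further normalization, and a probe set was tested if its ratio was at least 1 on at least 4 of the 9 arrays of its type. This stands in for the planned filter if low probe sets were divided by a fixed minimum, and was chosen after seeing the data. A first filter, a median ratio of at least 1, was also tried on the data and then replaced, because the median lies within the larger A2B5+ group and the filter left out genes measured mainly in O4+ cells, among them Cldn11, Gjb1, Hapln2 and Opalin. It is kept among the alternatives. The filter in use kept 13098 of 15866 probe sets that are not controls on array A and 11136 of 15276 on array B. On each type 57 control probe sets were left out of the tests. No value had to be offset before taking log2.

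Probe sets were named through the platform annotation given for this work. On array A 12789 probe sets had 1 gene symbol, 312 had several and 2822 had none. On array B these numbers were 7570, 100 and 7663. Of the probe sets with 1 symbol, 12754 and 7530 were matched through gene identifiers to the reference gene table, and 0 symbols changed. No gene was named from a probe set with several symbols. One row per gene was made as the mean log2 ratio of its tested probe sets with 1 symbol, with array A used before array B, which gave 9045 genes from array A and 2937 from array B. Columns of both types were set side by side by replicate number. This does not change a gene's own test, but the numbers of the O4+ arrays do not match across types on 100 shared probe sets, which bears on correlations between genes of different types. Among 1911 genes with several such probe sets, 27 had probe sets called in opposite directions.

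O4+ was compared with A2B5+ with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), separately on each array type and once on the rows per gene. P-values were adjusted by Benjamini-Hochberg within each fit, and a difference was called at an adjusted p under 0.05. Values are log2 differences, O4+ minus A2B5+, with the standard error of the fit. The p-values measure the spread between replicates of a population, and the test treats all replicates as independent.

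The 29 gene lists were fixed before the data were examined. Each was tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over the 29 lists, and again with a correlation estimated from the data. A list's shift is its median log2 difference minus the median of all genes, 0.14. As a test chosen after seeing the data, the mean of a list's array A genes, on arrays centred on their medians, was compared between populations by an exact permutation test over the 126 splits into 5 and 4 arrays (two-sided), with Benjamini-Hochberg adjustment over the 29 lists. Unlike camera, it asks whether a list's mean differs between populations, not whether it differs more than that of other genes.

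Genes were named by a rule fixed beforehand. It takes, per array type, the 5 largest rises and 5 largest falls among called probe sets whose populations do not overlap; per list, up to 4 members with the smallest p and up to 2 more called against the list's median; and a fixed set of lineage genes. Of the genes this rule gives, part are described in the text. Genes described outside it are said to be chosen after their values were seen.

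Spike-in controls, a 5S rRNA probe set and the differences between 5' and 3' probe sets of Gapdh and beta-actin were read per array as signs of array and RNA quality. The alternatives tried were no filter, a filter on the median ratio, quantile normalization, median centring, array weights, a replicate block, each replicate left out, a robust variance model, leaving out the O4+ array with high control signal on each type, 0.25 added to each ratio, other thresholds and other set tests. A stricter filter on level, an offset of 16 on the linear scale and an intensity trend in the variance were planned but not run, since ratios hold no level.

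The limma step was tested on simulated data with 200 changed probe sets and the real probe sets' spread. On the simulated array A data of 13098 probe sets, 90.9% of 4-fold changes, 59.7% of 2-fold changes and 16.4% of 1.5-fold changes were recovered. On the simulated array B data of 11136 probe sets, these shares were 83.3%, 55.2% and 29.9%. False calls made up 5.13% and 6.67% of calls. In simulated data for 29 lists of independent genes, the 1 list that was shifted was called and 0 others were. Genes of real lists were correlated (estimated at 0.63 for ribosomal protein genes), and far more than 200 probe sets were called in the real data. The simulations cover neither case. Figures were drawn with matplotlib 3.10.9.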

Results

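Expression was measured in A2B5+ and O4+ cells from the brains of male rat pups at postnatal day 7. A2B5 is an antibody against gangliosides on the surface of glial progenitors, and of some neurons. O4 is an antibody against sulfatide and related lipids that marks late progenitors and oligodendrocytes. The data comprised 5 replicates of A2B5+ cells and 4 of O4+ cells, each from a litter of pups, on each of 2 array types. Whether A2B5+ and O4+ replicates shared litters was not settled. The comparison asks which transcripts differ between these sorted populations. The populations may also differ in their shares of other cell types, which the differences below cannot separate from changes within lineage cells. All values are log2 differences, O4+ minus A2B5+, with the standard error of the limma fit and n = 5 and 4.

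O4+ cells carried far more transcript of most myelin genes, more of most cholesterol synthesis genes and less of most cell cycle genes than A2B5+ cells. With an estimated correlation the calls of the cholesterol and cell cycle lists were lost (adjusted p = 0.25 and 0.14), and that of the myelin list held (adjusted p = 0.026) but was lost once O4+ arrays were matched across array types (adjusted p = 0.15). Among called probe sets with 1 gene symbol and no overlap between the populations, the largest fitted rises on array A were Mobp, a basic protein of compact myelin (7.68 ± 0.37, 206-fold, adjusted p = 4.7e-07), Hapln2, a matrix protein of nodes of Ranvier (at least 5.88), Mal, a proteolipid of myelin membrane traffic (6.96 ± 0.38), Klk6, a protease of mature oligodendrocytes (6.40 ± 0.31), and Mbp, a main structural protein of myelin (6.21 ± 0.20 for 1 of its probe sets). By the same rule, the leading rises on array B were Ermn, a cytoskeletal protein of oligodendrocytes (7.20 ± 0.27), Slc5a11, an inositol transporter (5.74 ± 0.17), Ano4 (5.22 ± 0.37), Opalin, a myelin glycoprotein (at least 4.04), and Nfasc, an adhesion molecule of the node and paranode (5.10 ± 0.95 for 1 probe set). On array A, Nfasc rose by only 1.97 ± 0.14 as the mean of 3 probe sets. Ermn on array B rose by 6.46 ± 0.20 as the mean of 2 probe sets. For Hapln2 and Opalin the A2B5+ ratios were at most 0.472 and 0.465 and varied little (residual SD 0.11 and 0.012), so only a bound is given, the O4+ mean over a ratio of 1. The fitted differences that placed them here were 7.13 ± 0.29 and 5.17 ± 0.37. The falls were smaller in log2 terms. On array A the falls chosen by this rule were led by Gad1, which makes GABA in inhibitory neurons (-4.08 ± 0.73), and the Eph receptor Epha4 (-4.05 ± 0.45 for 1 probe set, -3.245 ± 0.38 as the mean of 2). Next among these falls came the mast cell protease Mcpt1l1 (-4.02 ± 0.44), Myzap (-3.96 ± 0.22) and Cpa3, a mast cell carboxypeptidase (-3.77 ± 0.43). On array B those with 1 gene symbol were led by Sox18, a transcription factor of endothelial cells (-3.85 ± 0.48), Aspm, a spindle protein of dividing progenitors (-3.67 ± 0.20), the polysialyltransferase St8sia4 (-3.63 ± 0.48), Ccno, needed for multiciliated cells (-3.60 ± 0.76), and Dach1 (-3.60 ± 0.32).

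On array A, 4259 of 13098 probe sets were higher and 1929 were lower in O4+ cells at an adjusted p under 0.05, with 7506 at an unadjusted p under 0.05. On array B, 1106 of 11136 were higher and 1538 lower, with 4115 at an unadjusted p under 0.05. The values of both populations did not overlap for 44.0% of probe sets on array A and 25.6% on array B, where chance gives 1.59%. The first principal component held 66.0% of the variance on array A and 62.1% on array B and separated both populations. On array A the excess of higher calls, 68.8% of those made, depended on the scale of the arrays. The tested probe sets of O4+ arrays had a median 0.17 above that of A2B5+ arrays, and centring each array on its median gave 2439 higher and 2344 lower, or 51.0% higher. On array B centring left the split close to where it was, at 41.8% before and 41.7% after. Array medians there differed by only 0.0024 between the populations, so centring could change little. Array A values given here include that shift of 0.17, and a named gene whose call ends when it is removed is said to do so. The median difference of tested probe sets on array A was 0.256, and still 0.086 after centring. Centring may thus leave part of a scale shift in place.

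Myelin genes rose almost as a whole. Of 30 tested genes for myelin proteins and mature oligodendrocytes, 28 were higher and 0 lower, both over all genes and adjusted over the list alone. The list's shift was 3.48 (camera adjusted p = 6.3e-16; adjusted p = 0.026 with an estimated correlation). The last call was lost, at an adjusted p = 0.15 with an estimated correlation, once the O4+ arrays of both types were matched by their shared probe sets in place of their numbers, a setting chosen after seeing the data. Enpp6, an enzyme of newly formed oligodendrocytes, rose by 4.19 ± 0.12, Mag, an adhesion protein of the inner myelin membrane, by 4.87 ± 0.18, Mog, a protein of the outer myelin surface, by 5.58 ± 0.33, and Cnp by 3.68 ± 0.38. Mbp rose by 4.48 ± 0.15 as the mean of 2 probe sets, or 22.3-fold. The list mean on array A was -0.63 ± 0.16 (SD, n = 5) in A2B5+ cells and 2.78 ± 0.32 (SD, n = 4) in O4+ cells (exact permutation p = 0.0079, the smallest that 126 splits allow; adjusted p = 0.019).

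**Figure D1:**
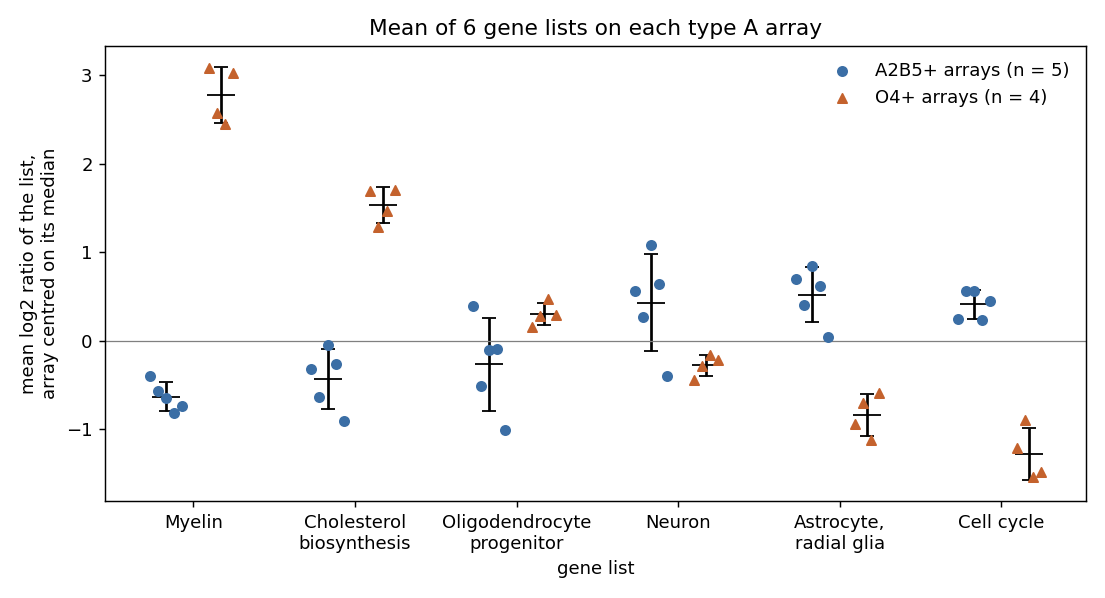
Mean log2 ratio of the array A genes of 6 gene lists, on arrays centred on their medians. Each point is an array (circles, 5 A2B5+; triangles, 4 O4+), and bars show the mean and SD. The O4+ arrays lie between 2.45 and 3.08 for myelin genes, above all A2B5+ arrays, and between -1.53 and -0.89 for cell cycle genes, below all of them; for progenitor and neuron lists the populations overlap.

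Cholesterol synthesis genes rose almost as a whole, and genes of other lipids moved both ways. In cholesterol biosynthesis, 20 of 22 tested genes were higher and 0 lower, with the same counts adjusted over the list alone, and the list's shift was 2.03 (camera adjusted p = 2.1e-09; adjusted p = 0.25 with an estimated correlation; exact permutation adjusted p = 0.019). Mvd, Lss and Idi1, enzymes of the path from mevalonate to lanosterol, rose by 2.56 ± 0.13, 3.00 ± 0.18 and 2.75 ± 0.17. In fatty acid and sphingolipid synthesis, 17 of 32 were higher and 3 lower (18 and 3 adjusted over the list alone; shift 0.45, camera adjusted p = 0.0010; adjusted p = 0.30 with an estimated correlation). Its risers included Ugt8, which makes galactosylceramide (5.38 ± 0.64), Gal3st1, which turns it into sulfatide, the lipid that O4 recognises (4.27 ± 0.25), Fa2h, which hydroxylates its fatty acid (4.30 ± 0.35), and the long-chain elongase Elovl1 (2.84 ± 0.11). The acyl-CoA synthetases Acsl6 and Acsl5 fell by 1.70 ± 0.40 and 0.69 ± 0.25. Of 10 tested genes of ganglioside synthesis, whose products A2B5 recognises, 6 were higher and 3 lower (7 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.58). The sialyltransferases St8sia5 and St6galnac3 rose by 2.21 ± 0.29 and 2.78 ± 0.38, and St3gal2 fell by 1.95 ± 0.20.

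Cell cycle genes fell almost as a whole. Of 49 tested, 45 were lower and 0 higher, also adjusted over the list alone, with a shift of -1.81 (camera adjusted p = 1.1e-22; adjusted p = 0.14 with an estimated correlation; exact permutation adjusted p = 0.019). The mitotic kinase Bub1 fell by 3.10 ± 0.14, the cyclin-dependent kinase Cdk1 by 2.40 ± 0.17, the topoisomerase Top2a by 2.07 ± 0.22 and the proliferation marker Mki67 by 2.27 ± 0.24, the last being 4.82-fold.

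Genes of oligodendrocyte progenitors moved both ways. Of 19 tested, 9 were higher and 5 lower (10 and 5 adjusted over the list alone), and the list was not called (shift 0.45, camera adjusted p = 0.58; exact permutation adjusted p = 0.13). Its shift was 0.24 without O4+ replicate 2. Pdgfra, the growth factor receptor that marks progenitors, fell by 2.29 ± 0.61 with overlap between the populations, and the proteoglycan Cspg4, also called NG2, fell by 0.95 ± 0.30. Ptprz1 and Cspg5, also progenitor surface proteoglycans, fell by 0.85 ± 0.15 and 1.38 ± 0.31. Sox10, a transcription factor of the whole lineage, rose by 4.68 ± 0.61, Olig1 2.83-fold (adjusted p = 0.0061), and the matrix proteins Vcan and Tnr by 1.99 ± 0.34 and 4.26 ± 0.75. Among 32 tested transcription factors of the lineage, 12 were higher and 7 lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.82). The list's median lay 0.11 below that of all genes while its mean difference (0.57) and its camera test pointed upward. Myrf, which switches on myelin genes, rose by 3.84 ± 0.33, Nkx6-2 by 4.77 ± 0.19 and Tcf7l2 by 2.58 ± 0.20, and Id4, an inhibitor of differentiation, fell by 1.26 ± 0.25. Id2 had a difference of 0.04 ± 0.24 (adjusted p = 0.89). Gpr17 and Hmgcs1 had no probe set with 1 symbol here, and the probe sets of Olig2 and St8sia1 lay below the filter.

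**Figure D2:**
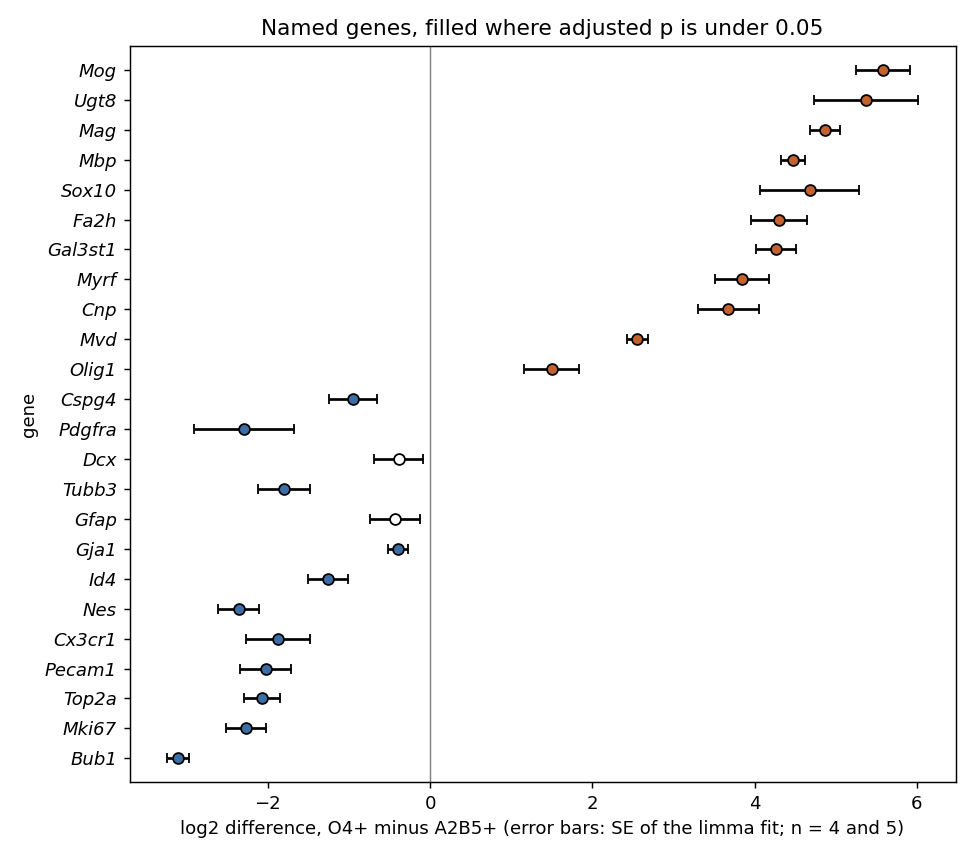
Log2 difference, O4+ minus A2B5+, of 24 named genes, with the SE of the limma fit as bars (n = 4 and 5). Filled points have an adjusted p under 0.05 and open points do not; myelin and lipid genes lie to the right, from 2.56 for Mvd to 5.58 for Mog, and proliferation markers to the left, down to -3.10 for Bub1.

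Markers of astrocytes and radial glia, microglia, and endothelial and mural cells were mostly lower in O4+ cells. Of 28 tested astrocyte and radial glia markers, 18 were lower and 1 higher (20 and 1 adjusted over the list alone), with a shift of -1.46 (camera adjusted p = 6.1e-08; adjusted p = 0.25 with an estimated correlation; exact permutation adjusted p = 0.019). The 1 higher, Aldh1a1 (0.42 ± 0.11), was no longer called after centring (adjusted p = 0.096). Nes, the intermediate filament nestin of neural progenitors, fell by 2.36 ± 0.25 and Mlc1, an astrocyte membrane protein, by 2.29 ± 0.28, while Gfap differed by -0.43 ± 0.31 (adjusted p = 0.27). Of 26 microglia markers 21 were lower and 0 higher, also adjusted over the list alone (shift -1.31, camera adjusted p = 2.0e-07; adjusted p = 0.48 with an estimated correlation; exact permutation adjusted p = 0.019). The receptors Csf1r and Cx3cr1 fell by 1.36 ± 0.24 and 1.87 ± 0.40. Of 29 endothelial and mural cell markers 17 were lower and 0 higher, also adjusted over the list alone (shift -1.32, camera adjusted p = 3.4e-07; adjusted p = 0.45 with an estimated correlation; exact permutation adjusted p = 0.019). The angiopoietin receptor family members Tie1 and Tek fell by 2.56 ± 0.23 and 2.27 ± 0.25, and the endothelial adhesion protein Pecam1 by 2.02 ± 0.32.

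Neuron and neuroblast markers moved both ways, with 15 of 37 lower and 8 higher (16 and 9 adjusted over the list alone; 15 and 5 with arrays centred). The list was not called (shift -0.53, camera adjusted p = 0.075; exact permutation adjusted p = 0.10), but leaving out A2B5+ replicate 5 gave a call (adjusted p = 0.0064), as did leaving out A2B5+ replicate 2 (0.047) or O4+ replicate 3 (0.046). The neuronal tubulin Tubb3 fell by 1.81 ± 0.32, and Nsg1 and Nrgn fell by 1.98 ± 0.14 and 2.27 ± 0.26. The stathmin Stmn4 rose by 3.49 ± 0.26, the enolase Eno2 by 2.39 ± 0.26 and Elavl3 by 1.36 ± 0.24. Dcx, a marker of migrating neuroblasts, differed by -0.39 ± 0.30 (adjusted p = 0.31). The remaining 3 cell type lists were not called. Of 10 ependymal and choroid plexus markers 3 were lower and 0 higher (camera adjusted p = 0.58), of 7 blood cell markers 4 were higher and 2 lower (0.90; list median 0.40, mean -0.02, camera test upward), and of 6 Schwann cell markers 4 were higher and 1 lower (0.17), with the same counts adjusted over the list alone except for 5 higher Schwann cell markers. Those rises included Prx (3.43 ± 0.33) and Pmp22 (2.28 ± 0.42), both genes of peripheral myelin. With arrays centred, 0 blood cell markers were higher and 2 lower, and 3 Schwann cell markers were higher and 1 lower.

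Many genes of oxidative phosphorylation and of the proteasome rose modestly. Of 75 oxidative phosphorylation genes, 42 were higher and 1 lower (47 and 1 adjusted over the list alone; shift 0.46, camera adjusted p = 3.5e-06; adjusted p = 0.70 with an estimated correlation). Of 36 proteasome genes, 25 were higher and 1 lower (28 and 1 adjusted over the list alone; shift 0.38, camera adjusted p = 3.4e-04; adjusted p = 0.45 with an estimated correlation). With arrays centred the higher counts were 29 and 15. Ndufv2 of complex I rose by 1.14 ± 0.17 and Psmd7 of the proteasome lid by 1.08 ± 0.16. O4+ replicate 2 on array A, which had the highest spike-in and 5S rRNA signal, also had the highest mean of both lists, 0.68 and 0.52 against 0.04 to 0.32 and 0.06 to 0.21 in the other O4+ arrays. Without O4+ replicate 2 the shift of the oxidative phosphorylation list was 0.28 (adjusted p = 2.0e-04) and that of the proteasome list 0.31 (adjusted p = 0.0015). Of 41 ribosomal protein genes 0 were called by limma in either direction, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.87). In myelin trafficking and membrane fusion, 16 of 30 were higher and 7 lower (18 and 7 adjusted over the list alone; shift 0.42, camera adjusted p = 0.018; adjusted p = 0.25 with an estimated correlation), with Tppp, a tubulin-binding protein of oligodendrocytes, up by 4.64 ± 0.20. Of 24 dissociation and stress response genes 10 were lower and 1 higher, also adjusted over the list alone (shift -0.74, camera adjusted p = 0.0049; adjusted p = 0.62 with an estimated correlation; exact permutation adjusted p = 0.10). With array weights this list's shift was -0.28 and was not called (adjusted p = 0.083). On array A with arrays centred, its mean was 0.64, 0.44 and 0.76 in A2B5+ replicates 1, 2 and 5, which also had the highest means of motile cilia genes. It was -0.20 and -0.17 in A2B5+ replicates 3 and 4, within the range of the O4+ arrays (-0.72 to -0.08). The immediate early gene Egr1 fell by 1.26 ± 0.13 and Ddit4 rose by 1.05 ± 0.20.

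**Figure D3:**
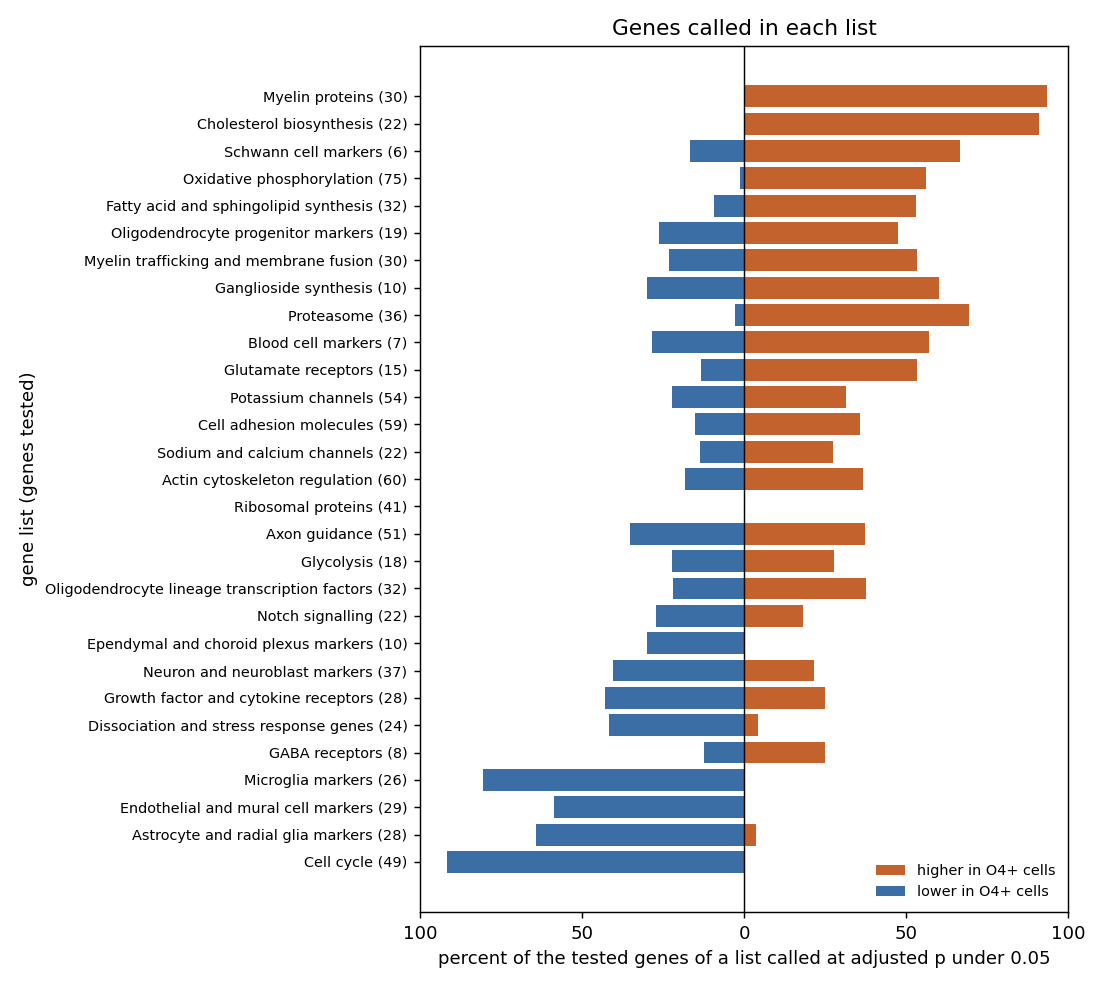
Percent of the tested genes of each of 29 lists called higher (right) or lower (left) in O4+ cells at an adjusted p under 0.05, with the number tested in brackets and lists ordered by their shift. Myelin proteins (28 of 30) and cholesterol biosynthesis (20 of 22) stand at the top and cell cycle (45 of 49 lower) at the bottom.

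Surface receptors, channels and guidance genes changed in both directions, and none of these lists was called by camera. Of all 11982 genes tested, 3445 were higher and 2127 lower, or 2241 and 2447 after centring. List counts near those shares are not particular to a list. Counts higher and lower were 21 and 9 of 59 for cell adhesion molecules (adjusted p = 0.41), 22 and 11 of 60 for actin regulators (0.58), 19 and 18 of 51 for axon guidance (0.68), 17 and 12 of 54 for potassium channels (0.58), 6 and 3 of 22 for sodium and calcium channels (0.93), 8 and 2 of 15 for glutamate receptors (0.17), 2 and 1 of 8 for GABA receptors (0.39), 4 and 6 of 22 for Notch signalling (0.29), 7 and 12 of 28 for growth factor and cytokine receptors (0.053) and 5 and 4 of 18 for glycolysis (0.87). Adjusted over the list alone, the counts that differed were 23 and 13 for actin regulators, 20 and 18 for axon guidance, 24 and 13 for potassium channels, 1 and 1 for GABA receptors and 5 and 5 for glycolysis. After centring, 4 potassium channel genes were higher and 13 lower, 1 sodium or calcium channel gene was higher and 3 lower, and 4 glutamate receptor genes were higher and 2 lower. Centring also gave 2 and 5 for glycolysis and 1 and 2 for GABA receptors, both turned toward lower, 4 and 13 for growth factor and cytokine receptors, 2 and 6 for Notch signalling, 18 and 11 for cell adhesion molecules, 19 and 17 for actin regulators and 14 and 18 for axon guidance. The growth factor receptor list (shift -0.68) was called after centring (adjusted p = 0.049), and also without A2B5+ replicate 2 (0.033), A2B5+ replicate 5 (0.027) or O4+ replicate 4 (0.035), but with no filter on low values its shift was -0.018 and was not called (adjusted p = 0.31). For axon guidance the camera test pointed downward while the median and mean differences were 0.13 and 0.12, and for glycolysis it did so while they were 0.04 and 0.09. Large single changes included the semaphorin Sema4d (5.98 ± 0.16), the adhesion protein Ninj2 (5.93 ± 0.36), the potassium channel Kcna1 (4.34 ± 0.60) and the receptor kinase Tyro3 (3.47 ± 0.38) upward, and the growth factor receptors Egfr (-1.53 ± 0.25) and Kdr (-2.03 ± 0.26) downward. Numb, an inhibitor of Notch, fell by 1.99 ± 0.19, while Notch1 differed by -0.41 ± 0.22 (adjusted p = 0.15) and Hes5 by -0.45 ± 0.24 (adjusted p = 0.15).

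Of the 29 lists, 11 were called by camera, 6 upward and 5 downward, and 1, the myelin list, was also called with an estimated correlation, a call lost with matched O4+ arrays (adjusted p = 0.15). That number of lists was not unusual among other splits of the 9 replicates, since 40 of 100 splits, the real one included, gave at least 11. The other splits keep part of the difference between the populations, so this does not decide on chance. By the exact test chosen after seeing the data, 14 of 29 lists passed. These were the lists called by camera, except dissociation and stress response genes, and also Notch signalling (adjusted p = 0.019), Schwann cell markers (0.019), growth factor receptors (0.035) and cell adhesion molecules (0.049). The exact test does not set a list against other genes, and 44.0% of array A probe sets did not overlap between the populations. Passing it therefore does not make a list stand out. The array controls differed in part between the populations. The median of the spike-in controls differed by 0.82 on array A (exact permutation p = 0.032, adjusted p = 0.076) and by 0.47 on array B (p = 0.063, adjusted p = 0.13). The 5S rRNA signal was higher by 1.02 on array A (exact permutation p = 0.0079, adjusted p = 0.048), with 1 O4+ array at a ratio of 6.90 against 1.03 to 1.15 in the other O4+ arrays. Differences between 5' and 3' probe sets of Gapdh did not separate the populations (exact permutation p = 0.83 on array A and 0.79 on array B).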

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

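Of the tests in this part, the counts over splits of the samples were planned, and the others on scale, replicate order and other cell types were chosen after their results were seen. In 442 groups of 4 or 5 arrays, the highest or lowest array was tested for standing apart, by its gap to the nearest array over the range of the group (Dixon's ratio); 32 groups passed the 95% critical value where chance gives 22.1.

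On array A the 5S rRNA signal of O4+ replicate 2 lay above the other O4+ arrays (ratio 0.944). On array B the 5S rRNA and spike-in signals of O4+ replicate 4 lay above the others (0.898 and 0.905). The Gapdh 5' to 3' difference of A2B5+ replicate 5 lay below the others on array B (0.737). On array A, O4+ replicate 2 lay above the other O4+ arrays for Stmn4 (0.914), Notch3 (0.9), Gabre (0.86), Kcnj5 (0.88), Rps3 (0.844) and the probe set of Myzap (0.847). With arrays centred, the calls of Notch3 and Gabre ended (adjusted p = 0.18 and 0.23). It lay below them for Eno2 (0.886), Rbpj (0.864) and Kcna1 (0.839). The array B O4+ array numbered 4 lay below the others for Elavl3 (0.865) and the probe set of Nfasc (0.896). The array A O4+ array numbered 4, which by the matching of both types need not be the same litter, lay above the others for Mlc1 (0.838). On array A, O4+ replicate 3 lay below for Alas2 (0.893) and Mog (0.868) and above for Psmd6 (0.838), and O4+ replicate 1 lay below for Pecam1 (0.842).

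A2B5+ replicate 1 lay above the other A2B5+ arrays for the myelin lipid enzymes Gal3st1 (0.877) and Fa2h (0.895), for Myrf (0.747) and for Sh3gl3 (0.711), and below them for Mki67 (0.725). A2B5+ replicate 5 lay below for Mbp (0.852), Jam2 (0.784), Myh10 (0.777), Pfkp (0.766) and Slc2a1 (0.713). A2B5+ replicate 2 lay below for Pmvk (0.791) and A2B5+ replicate 4 for Cox6b2 (0.725).

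The excess of higher calls on array A, 68.8%, goes with the scale of the arrays. Probe sets below the filter were higher in O4+ cells by a median of 0.311 on array A and 0.0645 on array B, so a scale difference between the populations may account for the excess. It rests on low probe sets carrying little signal of their own; those with a median ratio under 1 on array A followed a shared pattern over the arrays with a median residual SD of 0.065, against 0.39 in other probe sets. Over the 100 probe sets shared by both types, the O4+ minus A2B5+ difference was higher on array A by a mean of 0.295 (SD 0.088). It had the same sign on both types for 69 of them. The same populations were compared on both types, so this offset argues for a scale difference between the types. It does not tell which type carries the offset. Whether more genes were also truly higher cannot be told. Centring, which gave 51.0% higher calls, takes off a shift of the array medians whatever its source, and may leave part of a scale shift.

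The O4+ replicate numbers did not match between array types. Over 100 shared probe sets, same-numbered O4+ arrays had a mean correlation of -0.397, the lowest of 24 orders, while the order 3, 4, 1, 2 on array B gave 0.865, which is consistent with another numbering on that type. Noise in the shared probe sets is argued against, since 5 of 5 A2B5+ arrays correlated best with their own number. These correlations are across probe sets, which are not independent replicates. No biological explanation was tested.

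Markers of microglia, endothelial and mural cells, and astrocytes and radial glia were lower in O4+ cells, while camera called none of the neuron, blood, ependymal and Schwann cell lists, the last of which passed the exact test (adjusted p = 0.019). Cells of the types that were lower, in varying share in the sorted samples, may contribute. Microglia markers varied together over replicates of a population (mean residual correlation 0.660, against 0.0996 at the 95th percentile of random lists), as did endothelial and mural markers (0.443 against 0.0921) and astrocyte and radial glia markers (0.208 against 0.0917). The test is not specific to cell shares, as ribosomal protein genes varied together too (0.679). A lower share of lineage cells in the A2B5+ sort, raising all other types alike, cannot be told apart from separate changes, as the intervals of the 6 list medians all overlapped (gap -0.123). These intervals came from resampling the genes of each list, not the arrays, so they hold no spread between replicates. Lower expression in the lineage cells themselves stays open and untested.

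Among 100 splits of the 9 arrays into 5 and 4, drawn with the real one included, 1 gave as many called probe sets as the real split on array A (6188, highest other 2061), 1 on array B (2644, highest other 823) and 1 as many called genes (5572, highest other 1995). Chance is argued against for these counts but not excluded, as 1 in 100 is the smallest share possible here. Splits that mix the populations put their difference into the spread, and most gave no calls. The scale shift on array A is part of its count, and splits do not address it. For the number of lists called by camera, 40 of 100 splits gave as many (11, highest other 16). No other split into 5 and 4 balances the populations, so each keeps part of their difference. That count of splits therefore cannot decide whether chance gives the number of lists.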

How the results depend on the processing

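The order matching of O4+ arrays, the median filter, the addition of 0.25, the robust model, 1 probe set per gene and leaving out the arrays with high control signal were chosen after seeing the data; the other settings were planned. On array A, higher probe sets (4259) became 7128 with no filter, 2131 with quantile normalization, 2439 with centring, 2094 at an adjusted p under 0.01 and 1431 at 2-fold or more. Lower ones (1929) became 1164 and 1211 under the last 2 settings. On array B, higher ones (1106) became 574 and 659, and lower ones (1538) 779 at an adjusted p under 0.01. The cause was not tested beyond the stricter thresholds.

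With 1 replicate left out, the counts lay at 3015 to 4678 and 1628 to 1969 on array A, and 807 to 1292 and 1124 to 1629 on array B. The neuron list, not called at -0.53, was called with no filter (-0.44), with array weights (-0.89) and with array A genes (-0.62). It ranged from -0.77 without A2B5+ replicate 5 to -0.36 without A2B5+ replicate 3. With an estimated correlation, with or without matched O4+ arrays, the shifts of astrocyte (-1.46), cell cycle (-1.81) and cholesterol (2.03) lists were no longer called; the myelin list (3.48) lost its call with matched arrays only. Rab27a, called lower, had a difference of 0.30 with no filter. The cause was not tested.

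Whether the shared replicate numbers pair A2B5+ and O4+ samples was not settled. Same-numbered arrays correlated at 0.02 to 0.31 on array A and -0.20 to 0.24 on array B. On each type, 1 of 4 O4+ arrays correlated best with its own number. The O4+ numbers disagree between types, so on at least 1 type this check could not have shown a pairing. No other order of the O4+ arrays was tried against the A2B5+ arrays. With the replicate number as a block, the neuron list's shift was -0.77 and called (adjusted p = 0.0071), as was that of growth factor receptors (0.037). A2B5+ replicate 5 has no O4+ partner and so does not count in that fit; leaving it out without a block gave the same shifts and both calls (0.0064 and 0.027), so the calls are not owed to the block.

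Of 3274 comparisons of 182 named results with an alternative, 3142 kept their side of the threshold, 113 lost the call, 18 gained it and 1 reversed. A change of direction counted as a reversal only where the result was called in the main fit or in the alternative. Leaving out the O4+ array with high control signal on each type changed the call of 0 of 29 lists. A stricter filter on level, an offset of 16 and an intensity trend were not run, as ratios hold no level; signal over background is not recorded.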

Other observations

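The gene groups here were put together after their leading members were seen among the strongest falls, so their counts are descriptions, and all tests in this part were chosen after the results were seen. Genes of mast cells were lower in O4+ cells, with 11 of 15 tested genes lower and 1 higher and a median difference of -1.49. The proteases Cma1 and Tpsab1 fell by 3.56 ± 0.52 and 2.58 ± 0.53, the histamine enzyme Hdc by 2.58 ± 0.51 and the IgE receptor chain Fcer1a by 2.64 ± 0.52. The O4+ values of Tpsab1 varied as little as those of low probe sets (residual SD 0.045), so the size of its fall is uncertain if they lie at background. The protease Mcpt4 was higher by 0.54 ± 0.20, a call that ended with arrays centred (adjusted p = 0.13). All 15 were from array A, and the means here are log2 ratios on arrays centred on their medians. The mast cell mean was 1.35 and 1.48 in A2B5+ replicates 2 and 5, 0.44, -0.0096 and 0.60 in A2B5+ replicates 1, 3 and 4, and -1.32 to -0.77 in O4+ arrays. On array A, microglia markers were also highest in A2B5+ replicates 2 and 5 (0.79 and 0.70), against 0.06, 0.15 and 0.44 in A2B5+ replicates 1, 3 and 4. Mast cells in the A2B5+ sort are a candidate source, as a hypothesis; leaving out the 3 members among the strongest falls left 8 of 12 lower, 1 higher and a median of -1.27, so the picked members do not carry the whole pattern.

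Genes of motile cilia, carried by ependymal cells in the brain, were lower too, with 20 of 28 lower and 2 higher and a median of -1.84. The axonemal dyneins Dnah12 (-2.99 ± 0.62) and Dnah1 (-3.17 ± 0.73) fell, and Foxj1, the main regulator of motile cilia, fell by 1.52 ± 0.47. The mean of the 23 from array B was high in A2B5+ replicates 1, 2 and 5 (1.90, 1.64 and 1.52) and lower in A2B5+ replicates 3 and 4 (0.16 and -0.085), where O4+ arrays lay at -0.86 to -0.44. The 5 from array A had means of 1.37, 0.88 and 1.16 in the first 3 of these and -0.35 and -0.65 in the others, the last below all O4+ arrays (-0.61 to -0.075). Leaving out the 7 members among the strongest falls left 13 of 21 lower, 2 higher and a median of -1.46. Of 16 transcription factors and related genes of endothelial cells, 14 were lower and 1 higher with a median of -2.21, among them Sox7 (-3.10 ± 0.38), Sox17 (-3.58 ± 0.52) and Bcl6b (-2.80 ± 0.28). Gata2 (-0.82 ± 0.25) counts as lower both in this endothelial group and in the mast cell group. Leaving out the 7 members among the strongest falls left 7 of 9 lower, 1 higher and a median of -1.52.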
